A study of Mus musculus with 5 samples.

How the data were processed

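Single-cell RNA sequencing was done on CD45+ cells sorted from the thyroids of NOD mice, per the labels. The mice were 4 to 6 weeks old at the start and received anti-PD-1 plus anti-CTLA-4 antibodies (10 mg/kg per dose; immune checkpoint inhibition, ICI) or isotype control antibodies for 4 weeks. The series describes 16 mice in the ICI group and 10 in the isotype group, pooled into 4 ICI libraries and 1 isotype library. The labels do not say how many mice went into each library.

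The deposited count table holds whole-number UMI counts for 18767 genes in 10275 cells, and the sums per cell equalled the UMI totals of the authors' cell table in every cell. Per the submitters' processing notes, Cell Ranger and Seurat were used with mouse build mm10. The deposited cell table gives the mitochondrial percent of each cell (highest 25.0%), cell cycle scores and phase calls, and 17 clusters of the integrated data at resolution 0.4, per the file headers. The deposited score values for the cell cycle were used only to describe phase calls. Each cell was assigned to its library through the cell table.

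The authors' clusters were kept. Clusters were named after the data were seen, from 21 marker lists fixed before the data were examined. A name rests on the list's genes among the cluster's top 10 by fold over all other cells (pseudocount of 10 CPM, genes seen in at least 20% of its cells), or else on the list's genes at 1.5-fold or more. Clusters 0 and 11 had no gene of their lists among the top 10 and were named by the latter, with 4 of 8 CD4 T cell genes and 8 of 10 thymocyte genes. Cluster 2 had 1 thymocyte gene among its top 10 and 5 of 10 at 1.5-fold, beside 7 of 10 general T cell genes. Clusters 2 and 11 were joined as thymocyte-like. Clusters 3, 9 and 12 are given by number, and clusters 13 and 15 stayed unnamed. Clusters 0, 1, 3, 4, 6 and 9 were also joined, a set chosen after seeing the data. Its clusters 3 and 9 had 0 and 1 of 10 general T cell genes at 1.5-fold, while cluster 13, left out, had 3. Without clusters 3 and 9 the set held 53.7% of ICI cells and 19.2% of isotype cells. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared by exact two-sided permutation over libraries, whose smallest p is 0.2 with 4 libraries against 1. Benjamini-Hochberg adjustment ran over the cluster sets.

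Raw counts were summed per library over all cells and over each cluster set with at least 20 cells in the library. edgeR 4.0.16 fitted quasi-likelihood models with TMM scaling and filterByExpr (minimum count of 10), with Benjamini-Hochberg adjustment and a threshold of 0.05. The isotype library was assumed to vary as the ICI libraries do, so p-values measure spread between ICI libraries, and mice were pooled. The 24 gene lists were fixed before the data were examined and tested on log2 CPM values (prior count of 2) by camera with a correlation of 0.01 and by fry in limma 3.58.1, adjusted over lists within a set. Which lists the text describes was chosen after their values were seen. In data simulated for the sums over all cells, with 12659 genes, edgeR recovered 26% of genes changed 4-fold and 90% of those changed 16-fold, with 4 false calls among 120. DESeq2 made 51 false calls among 196 in the same data, 1 among 122 in data simulated for T-like cluster 1 and 14 among 140 for macrophage-like cluster 7, where edgeR made 3 among 119 and 9 among 132. The changed genes were drawn from the most abundant ones only. Simulated counts used the dispersion that edgeR fitted, independent libraries and no single cells with very high counts. Recovery and false calls may thus be worse in the real data.

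Named genes were, per comparison, the 10 largest folds in each direction (5 for single classes other than T, B and myeloid cells) among genes past the threshold with every ICI library on the same side of isotype. Receptor segments, mitochondrial genes, ribosomal protein genes and unnamed models were left out of this ranking. Il17a, Il17f, Ifng, Il21, Il22, Il23r, Gzmb, Pdcd1, Ctla4, Tnf and Foxp3 and up to 4 members of each described list were named whatever their result. Some genes that these rules cover are not reported here and are left out of the counts over named genes. Where a comparison called few genes, the others past the threshold are named too.

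Cells with a UMI of 7 genes were compared between clusters within the 4 ICI libraries by exact sign-flip permutation, whose smallest two-sided p is 0.125. Each cell was also thinned to 1000 UMIs, which left out 596 of 8923 ICI cells and 21 of 1352 isotype cells. Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no filter, each ICI library left out, ICI 1 to 3 summed, receptor, ribosomal and mitochondrial genes removed, called doublets removed, marker gates, pooled cells, an estimated correlation, and ICI 4 against isotype only for named genes. Scrublet in scanpy 1.11.5 called 16 of the 10275 cells (0.156%), too few for the caller to have worked, and no cell was removed from the main values. After seeing the data, further alternatives were added: the top 5% of doublet scores removed (511 cells), ICI 2 and 3 summed, the lower copy of each barcode those libraries share removed, each gene's highest cell left out, thymocyte-like and cycling-like clusters removed or left out of the denominator, thymocyte-like clusters added to the joint set or clusters 3 and 9 taken from it, cells with T and myeloid transcripts removed (all cells and macrophage-like cells), and ICI 4 against isotype only for shares and lists. For lists, ICI 4 against isotype was set against 10000 random lists matched on expression, from log2 ratios with a pseudocount of 2 CPM. Other tools were R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.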

Results

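Transcripts of CD45+ thyroid cells were counted in 4 libraries from ICI-treated NOD mice and in 1 library from isotype-treated mice. The ICI libraries held 1523, 1219, 1163 and 5018 cells, and the isotype library held 1352. The labels give 1688, 1234 and 1178 cells for ICI 1 to 3 and the same numbers as the table for the other libraries. Total depth was 4430929, 3858251, 4380351 and 32296759 UMIs in ICI 1 to 4 and 8130081 in isotype. ICI 4 and isotype shared features that ICI 1 to 3 lacked: Hbb-bs, a red cell globin, had 26385 and 3218 UMIs against 0 in each of ICI 1 to 3. Of the isotype Hbb-bs UMIs 94.8% lay in 3 cells, although 115 cells held at least 1. Xist, expressed in female cells, had 2563, 614 and 664 UMIs in ICI 1 to 3, 4 in ICI 4 and 0 in isotype. Eif2s3y, a Y-linked gene, was found in 4.53%, 17.6% and 19.3% of cells in ICI 1 to 3, 42.7% in ICI 4 and 37.7% in isotype. ICI 1 to 3 thus held transcripts of both sexes.

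The first comparison asked how the mix of infiltrating cells differed with treatment. T-lineage clusters 0, 1, 3, 4, 6 and 9 together made up 61.4% ± 1.61 (SD, n = 4) of ICI cells and 25.3% of isotype cells (95% interval 23 to 27.7). The size of this gap depends on the set, which leaves out the thymocyte-like clusters: with them it was 68.3% against 56.4%, a difference of 11.9 points in place of 36.1. Cycling-like cluster 5 is in neither sum. It had 8 of 10 thymocyte genes at 1.5-fold or more and held 4.66% of ICI cells against 11.3% of isotype cells. Adding it would narrow the gap further. T-like cluster 1, led by Gzmk, Ccl5, Ifng, Cxcr3 and Tbx21, genes of effector T cells, held 20.3% ± 9.29 against 3.33%. Regulatory T-like cluster 4, led by Foxp3 and Ctla4, held 7.41% ± 4.07 against 2.07%. Thymocyte-like clusters went the other way, with 6.94% ± 6.34 of ICI cells and 31.1% of isotype cells, and innate lymphoid type 2-like cluster 10 held 4.01% ± 1.83 against 8.65%. Each of these sets lay on the same side of isotype in all 4 ICI libraries.

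CD4 T-like cluster 0 held 14.6% ± 5.50 (SD, n = 4) against 8.80%, higher in 4 of 4 libraries. With thymocyte-like and cycling-like cells out of the denominator its difference fell from 5.76 to 1.78 points, with 2 of 4 libraries above isotype, and macrophage-like and natural killer-like shares were then lower in all 4. Cycling-like cluster 5 held 4.66% ± 4.30 against 11.3%, and conventional dendritic-like cluster 16 held 0.600% ± 0.260 against 2.07%, each lower in 4 of 4. Since cluster 5 also carried thymocyte genes, its lower share may not be separate from that of the thymocyte-like clusters. The gamma-delta or type 17 T-like cluster 6 spanned 1.24% to 21.2% of ICI cells around the isotype share of 4.96%. Macrophage-like cluster 7 (9.13% ± 6.55 against 9.54%) and natural killer-like cluster 8 (5.49% ± 2.84 against 5.62%) lay on both sides of isotype. Cluster 3 (5.41% against 4.22%), cluster 9 (2.22% against 1.92%), cluster 12 (2.03% against 3.25%), cluster 13 (3.44% against 0.888%), B-like cluster 14 (1.58% against 1.18%) and cluster 15 (0.779% against 1.04%) did so too. No share passed the test: exact permutation p was 0.2 for the joint T-lineage set, cluster 1, the thymocyte-like, cycling-like, type 2-like and dendritic-like sets, the smallest that 4 libraries against 1 allow, and the lowest adjusted p was 0.64. A gate on Cd3 transcripts turned the T-lineage difference to -2.65 points, and in ICI 4 alone cluster 1 lay 3.11 points above isotype in place of 16.9.

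**Figure D1:**
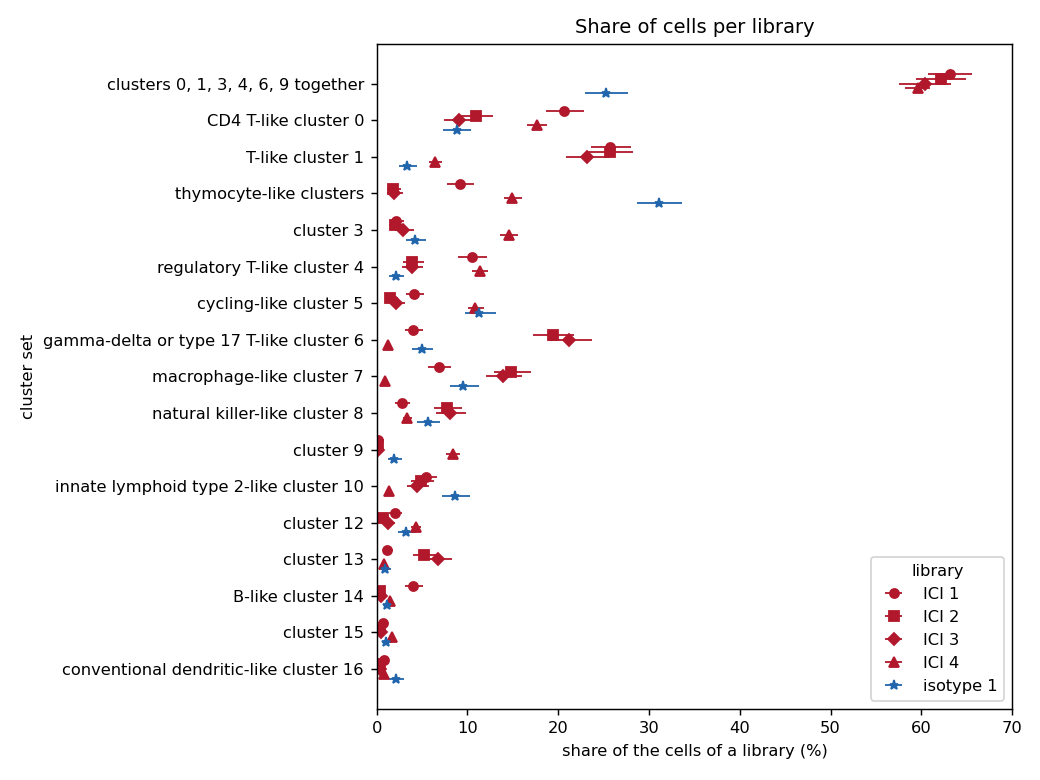
Share of the cells of each library (x axis, percent) in each cluster set (y axis), with red symbols for the 4 ICI libraries, blue for isotype and bars for exact 95% intervals. The joint T-lineage share lay between 59.6% and 63.2% in ICI and at 25.3% in isotype.

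The second comparison asked which genes differed over all cells. Class I antigen presentation genes, which load and display peptides for CD8 T cells, were higher in ICI: 12 of 12 measured members were above isotype in every ICI library, with a median log2 fold change of 1.04. H2-K1 was at 602 ± 470 CPM (SD, n = 4) against 129 in isotype, B2m at 2001 ± 680 against 913, and H2-D1 at 3498 ± 872 against 1726. The list passed camera (adjusted p = 6.22e-07) but not with a correlation estimated from the data (adjusted p = 0.556 with an estimated correlation), and 0 members passed when adjusted over the list alone. Resident macrophage genes had a median of -3.12 and 6 of 15 members were lower when adjusted over the list alone (camera adjusted p = 1.51e-05; adjusted p = 0.443 with an estimated correlation). The most abundant of them, Apoe, C1qa and C1qb, had log2 fold changes of 0.14, 0.76 and 0.78, and the sign for Apoe depended on the libraries. With cells holding both T and myeloid transcripts removed, the resident macrophage median was -1.88, with 6 of 14 folds positive.

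Fibroblast genes, which encode matrix proteins, and thymocyte genes, which act in T cell development, had negative folds in ICI. All 7 fibroblast genes were below isotype in every ICI library (median -3.91; camera adjusted p = 1.51e-05; adjusted p = 0.443 with an estimated correlation), with Dcn at 9.68 ± 19.4 CPM (SD, n = 4) against 206. All 10 thymocyte genes had negative folds (median -1.57; camera adjusted p = 0.00136; adjusted p = 0.556 with an estimated correlation), with Satb1 at 272 ± 298 against 774. All 24 proliferation genes (median -0.97) and 17 of 18 dissociation and stress genes (median -1.04) also had negative folds, with camera adjusted p = 0.000132 and 0.000123 and adjusted p = 0.556 for each with an estimated correlation. Endothelial genes had negative folds for 5 of 6 members (camera adjusted p = 0.000773; adjusted p = 0.443 with an estimated correlation), of which 3 passed when adjusted over the list alone. With the thymocyte-like and cycling-like clusters removed the medians were -1.97 for thymocyte, -1.36 for proliferation and -1.40 for stress genes. Cluster 12 stayed in, although it had 9 of 10 cycling cell genes at 1.5-fold or more. The proliferation value thus does not show these genes to be lower outside cycling cells.

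None of the genes named whatever their result passed over all cells (edgeR adjusted p of 0.817 or more, n = 4 against 1). Ifng, the type 1 effector cytokine, was at 64.4 ± 50.3 CPM against 13.7 and higher in 4 of 4 libraries, as were Foxp3 (25.8 ± 15.1 against 7.81) and Ctla4 (91.0 ± 64.5 against 44.8). Pdcd1, which encodes PD-1, was at 109 ± 40.7 against 50.3, and Gzmb at 60 ± 35.4 against 46.1. Il17a was at 20.3 ± 27.6 against 7.95 and higher in 2 of 4 libraries, ICI 2 and ICI 3, which may not be independent. Without ICI 3 its log2 fold change was -0.19. Il23r was at 21.3 ± 16.6 against 5.47, Tnf at 40.1 ± 25.8 against 79.3, Il17f at 0.653 ± 1.31 against 1.82 and Il22 at 1.15 ± 2.30 against 6.77. Il21 was at 1.05 ± 1.23 CPM in ICI, with 11 UMIs in ICI 1, 58 in ICI 4 and 0 in ICI 2, ICI 3 and isotype. Within T-like cluster 1, Ifng was lower in every ICI library. It was at 125, 260, 228 and 137 CPM (no TMM scaling) in ICI 1 to 4. In isotype it was at 279, from 9 cells with a UMI. Cluster 1 held 20.3% of ICI cells against 3.33%, so the all-cells Ifng difference does not show a rise within cells. Over all cells edgeR called 0 genes, with 516 at an unadjusted p under 0.05, while DESeq2 called 31, and edgeR called 210 without ICI 4. Counts without ICI 4, here and for the clusters, rest on the spread of ICI 1 to 3, of which ICI 2 and ICI 3 were nearly alike (140 shared barcodes).

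The third comparison asked which genes differed within clusters. In macrophage-like cluster 7, class I genes were higher in every ICI library for 12 of 12 members, and 9 passed when adjusted over the list alone (median 1.23; fry adjusted p = 0.0165; camera adjusted p = 2.13e-10; adjusted p = 0.138 with an estimated correlation). B2m was at 2354 ± 291 CPM (SD, n = 4) against 974, H2-D1 at 4169 ± 300 against 2026, and H2-K1 at 657 ± 337 against 146. Class II genes, which present to CD4 T cells, had 10 of 12 positive folds (median 0.71), of which 3 passed over the list alone, with fry adjusted p = 0.0165, camera adjusted p = 0.000572 and adjusted p = 0.373 with an estimated correlation. Interferon response genes had 24 of 26 positive folds (median 1.15; camera adjusted p = 2.33e-07; adjusted p = 0.373 with an estimated correlation), among them Bst2 at 429 ± 42.7 CPM against 170.

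In the same cluster, proliferation genes had 22 of 23 negative folds and 6 passed over the list alone (median -2.34; camera adjusted p = 2.27e-09; adjusted p = 0.373 with an estimated correlation), with Stmn1 at 67.2 ± 46.2 CPM (SD, n = 4) against 432. All 10 thymocyte genes were below isotype in every ICI library and 5 passed over the list alone (median -3.63; camera adjusted p = 5.58e-08; adjusted p = 0.438 with an estimated correlation). Cd8a, a T cell gene, was at 53.2 ± 68.2 against 426 in these macrophage-like cells. Their isotype cells were deeper, with a median of 9932 UMIs against 3403 to 8726 in ICI. edgeR called 0 genes in this cluster, with 766 at an unadjusted p under 0.05; DESeq2 called 15, and edgeR called 647 without ICI 4.

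Part of these changes went with cells that held both T and myeloid transcripts, 91 of 129 macrophage-like cells in isotype against 38 of 104, 17 of 181, 24 of 162 and 22 of 45 in ICI 1 to 4. With such cells removed, an alternative chosen after seeing the data, the class I median in macrophage-like cluster 7 fell from 1.23 to 0.60, with 12 of 12 folds positive (camera adjusted p = 0.00232). Class II, interferon response and proliferation genes lost their calls there (camera adjusted p = 0.165, 0.166 and 0.247), with medians of 0.42, 0.50 and -0.36 and 10 of the proliferation genes left to test. Deeper cells hold transcripts of both kinds more often, and depth was not equalised for this. Over all cells the class I median was 1 in place of 1.04.

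**Figure D2:**
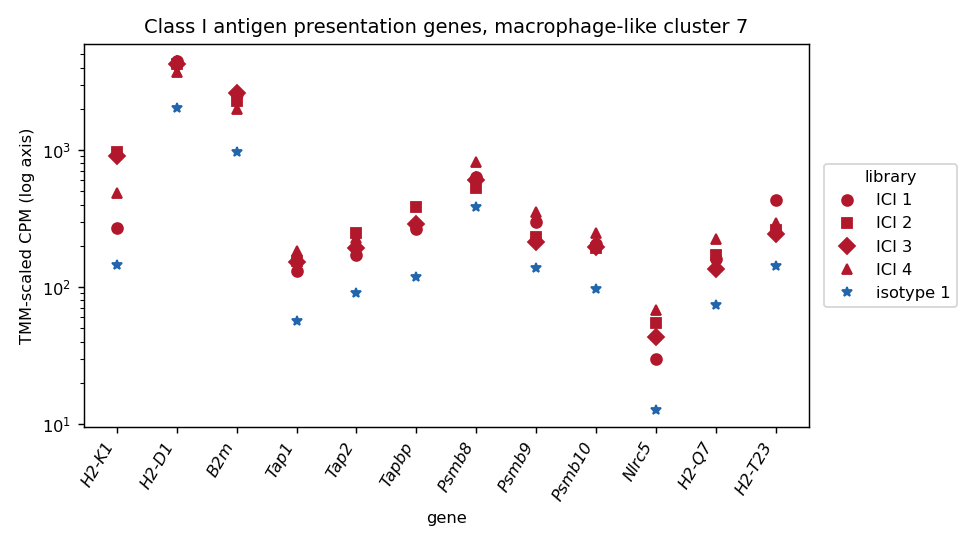
TMM-scaled CPM on a log axis (y) of the class I antigen presentation genes (x) in macrophage-like cluster 7, with red symbols for the 4 ICI libraries and blue for isotype. All 12 genes lay above isotype in each ICI library.

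Class I genes had positive folds in other clusters as well. All 12 were positive in the thymocyte-like clusters (median 1.28, 4 passing over the list alone), in clusters 0, 1, 3, 4, 6 and 9 together (median 0.56) and in cluster 6 (median 0.63), as were 11 of 11 in the type 2-like cluster 10 (median 0.61). Camera adjusted p was 6.75e-11, 0.000592, 0.000203 and 0.00446 in that order, against adjusted p = 0.341, 0.531, 0.558 and 0.392 with an estimated correlation. In the natural killer-like cluster 8, interferon response genes had 20 of 21 positive folds (median 0.73; camera adjusted p = 0.00162; adjusted p = 0.304 with an estimated correlation), with Irf1 at 227 ± 27.5 CPM (SD, n = 4) against 168. Class II genes went the other way in the type 2-like cluster 10, with 5 of 5 negative folds and 4 passing over the list alone (camera adjusted p = 2.64e-06; adjusted p = 0.392 with an estimated correlation). There, 75.5% of the isotype UMIs of Cd74 lay in 1 cell, and the list could not be tested with each gene's highest cell left out.

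Stress genes, induced by tissue dissociation, mostly had negative folds in these T-lineage sets: 17 of 18 in the joint set (median -1.36), 18 of 18 in cluster 6 (median -2.01) and 17 of 17 in regulatory T-like cluster 4 (median -1.23). Camera adjusted p was 1.04e-05, 2.75e-06 and 9.01e-09, against adjusted p = 0.540, 0.558 and 0.810 with an estimated correlation. Kdr and Egfl7, endothelial genes, had 0 UMIs in cluster 6 of the ICI libraries and 37 each in isotype, and 5 of 5 endothelial genes passed there over the list alone (camera adjusted p = 2.25e-11; adjusted p = 0.118 with an estimated correlation). In the joint set, 4 of 5 did (camera adjusted p = 2.22e-07; adjusted p = 0.531 with an estimated correlation). In cluster 4, 15 of 15 proliferation genes were below isotype in every ICI library (median -2.05, 5 passing over the list alone; camera adjusted p = 1.41e-14; adjusted p = 0.0557 with an estimated correlation). With each gene's highest cell left out, 5 of them could be tested and regulatory T-like cluster 4 lost this call (camera adjusted p = 0.0795). In cluster 1, thymocyte genes had 7 of 8 negative folds (camera adjusted p = 6.43e-05; adjusted p = 0.448 with an estimated correlation) and class II genes 6 of 7 (camera adjusted p = 0.00949; adjusted p = 0.475 with an estimated correlation). The class II call in T-like cluster 1 was lost with each gene's highest cell left out (camera adjusted p = 0.929), where H2-Eb1 and H2-Aa turned positive. In cycling-like cluster 5, cytotoxicity genes had 12 of 13 positive folds and resident macrophage genes 8 of 9 negative folds (camera adjusted p = 4.49e-06 and 4.17e-15; adjusted p = 0.405 and 0.226 with an estimated correlation).

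Single genes past the threshold outside cluster 12 were all lower in ICI. Tg, the thyroid hormone precursor, fell in cluster 1 (log2 fold change -8.50, SE 0.45, edgeR adjusted p = 0.000253), in the thymocyte-like clusters (-7.22, adjusted p = 5.89e-05) and in cluster 4 (-4.67, adjusted p = 0.00757). The epithelial keratins Krt8 (-8.96) and Krt18 (-6.06) and the regulators Atf3 (-7.10) and Klf4 (-5.19) also fell in cluster 4, as did Cd24a (-4.01). Ighg2b fell in the thymocyte-like clusters (-7.88), and the myeloid genes Cxcl2 (-8.93), Apoe (-7.53) and Lyz2 (-6.39) fell in cycling-like cluster 5. Each lay below isotype in every ICI library tested. The 3 cluster 5 calls were all lost without ICI 1 and with ICI 1 to 3 summed. They were also lost with the top 5% of doublet scores or the lower copies of shared barcodes removed. With DESeq2 both thymocyte-like calls were lost. For these 12 results a median of 97.9% of the isotype UMIs lay in 1 cell, against 14.4% for genes of like count. With each gene's highest cell left out, 1 of the 12 still passed, Tg in the thymocyte-like clusters (adjusted p = 0.00299), with log2 fold changes of -7.22 (SE 0.88) before and -6.05 (SE 1.32) after, and 8 fell under the filter. The other 3 could be tested and kept folds of like size with wider errors for each: Cd24a went from -4.01 (SE 0.64) to -3.56 (SE 1.38, adjusted p = 0.876), Apoe from -7.53 (SE 0.63) to -6.32 (SE 0.92, adjusted p = 1) and Lyz2 from -6.39 (SE 0.54) to -6.62 (SE 0.70, adjusted p = 0.362).

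Cluster 12, led by Nrgn, Tnfrsf9 and Tk1, had 13 genes higher and 17 lower in 2 ICI libraries against isotype. Foxp3, the regulatory T cell factor, rose to 83.8 ± 17.2 CPM (SD, n = 2) from 0 UMIs in isotype, and Gzmk to 47.4 ± 12.7 from 0. Il2ra, the high-affinity interleukin 2 receptor chain, rose to 153 ± 69.1 from 18.6, and Ly6a to 741 ± 227 from 114. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 of the class II list fell (log2 fold changes -3.90, -4.73, -4.91 and -3.76), as did Il1b (-8.48), Lyz2 (-7.49), Plbd1 (-7.02), Fcer1g (-3.98) and Tyrobp (-4.16), genes of myeloid cells. Pth, the parathyroid hormone gene, fell by 9.23 and Chga fell by 7.12, with 98.9% and 92.9% of their isotype UMIs in 1 cell. With each gene's highest cell left out, 15 of these 30 genes still passed (22 in all), among them Foxp3, Il2ra, Ly6a, Il1b, Lyz2, Tyrobp and the 4 class II genes, while Gzmk, Fcer1g, Plbd1, Pth and Chga did not. Jchain, at 170 ± 233 against 0, lost its call there too. Xist passed the threshold at 271 ± 383 against 0 but was above isotype in 1 of the 2 libraries only. Over all clusters, cells holding T and myeloid transcripts made up 3.74% of ICI 1, 2.35% of ICI 4 and 11% of isotype. Depth was not equalised for this. The removal of such cells was run for all cells and cluster 7 only. Whether the lower class II and myeloid genes of cluster 12 rest on such cells was thus not tested.

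For cluster 12 the class II list had 6 of 6 negative folds, the regulatory T cell list 8 of 10 positive folds and the checkpoint list 12 of 13 (camera adjusted p = 1.71e-08, 1.70e-05 and 2.67e-05; adjusted p = 0.634 for each with an estimated correlation). DESeq2 called 4 genes in place of 30, and no ICI library could be left out. edgeR called 0 genes in the joint T-lineage set (829 at an unadjusted p under 0.05; DESeq2 52), cluster 0 (287; DESeq2 0), cluster 3 (115; DESeq2 1), cluster 6 (572; DESeq2 7), natural killer-like cluster 8 (165; DESeq2 0) and type 2-like cluster 10 (157; DESeq2 0). Without ICI 4 it called 270, 55, 64, 1417, 325 and 483 in these sets. It called 1 gene in cluster 1 (DESeq2 5), 2 in the thymocyte-like clusters (DESeq2 0), 6 in cluster 4 (DESeq2 8) and 3 in cycling-like cluster 5 (DESeq2 8). Without ICI 4 edgeR called 58, 83, 68 and 203 there. Camera called 13 of the fixed lists over all cells, 8 in the joint set, 3 in cluster 0, 5 in cluster 1, 8 in the thymocyte-like clusters, 4 in cluster 3, 3 in cluster 4, 14 in cluster 5, 7 in cluster 6, 7 in cluster 7, 6 in cluster 8, 8 in cluster 10 and 9 in cluster 12, and 0 in each with an estimated correlation.

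The last comparison asked which cells carried Il17a, the cytokine in the series title. Il17a transcripts lay mainly in the gamma-delta or type 17 T-like cluster 6, led by Trdv4, Cd163l1, Tcrg-V6 and Blk. That cluster held 92.2% ± 5.83 (SD, n = 3 ICI libraries with a UMI) of the Il17a UMIs in ICI and 93.4% in isotype (95% interval 84.1 to 98.2). Of its cells, 4.19% ± 2.86 (SD, n = 4) had an Il17a UMI in ICI and 19.4% in isotype (95% interval 10.8 to 30.9). ICI 1 had 0 of 61 cells with an Il17a UMI, which allows a share of up to 4.92% of cells with a UMI and does not limit cells that express the gene. Macrophage-like cluster 7 had none in any library, with median depths of 3403 to 9932 UMIs against 3063 to 5498 in cluster 6.

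Thinned to 1000 UMIs, the shares of cluster 6 cells with an Il17a UMI were 3.11% in ICI and 11.9% in isotype. Within ICI, cluster 6 exceeded cluster 7 by 4.19 points, in 3 of 4 libraries. The exact sign-flip permutation p of 0.25 decides nothing. ICI 1 had 0 Il17a UMIs in all clusters, and 0.25 is then the smallest p possible. Il17a is also on the marker list from which cluster 6 was named. Pdcd1 was found in more cells of cluster 6 than of cluster 7 by 40.9 points ± 11.1 (SD, n = 4) and than of cluster 1 by 25 ± 5.27, in 4 of 4 libraries, with an exact sign-flip permutation p at the smallest value that 4 libraries allow for each. After thinning these differences were 19.7 and 8.09 points. Pdcd1 was not particular to cluster 6. In regulatory T-like cluster 4, 17.5%, 43.8%, 42.2% and 57.1% of cells had a Pdcd1 UMI in ICI 1 to 4. In cluster 6 the shares were 39.3%, 43.5%, 47.4% and 69.4%. After thinning they were 9.68%, 31.8%, 24.4% and 32.3% in cluster 4 and 12.8%, 18.4%, 19.3% and 37.1% in cluster 6. In isotype, unthinned, they were 42.9% and 46.3%. Clusters 4 and 6 were not compared by a test. Ifng was found in more natural killer-like cells than macrophage-like cells by 23.5 points ± 7.91 (SD, n = 4), also in 4 of 4 libraries, and by 7.78 after thinning. T-like cluster 1 exceeded macrophage-like cells in Ifng by 23.01 points, in 4 of 4 libraries, and by 10.55 after thinning. Of the Ifng UMIs in ICI 1 to 4, cluster 1 held 78.8%, 59.6%, 48.6% and 42.4%. Natural killer-like cluster 8 held 4.24%, 13.1%, 10.7% and 22.5%.

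**Figure D3:**
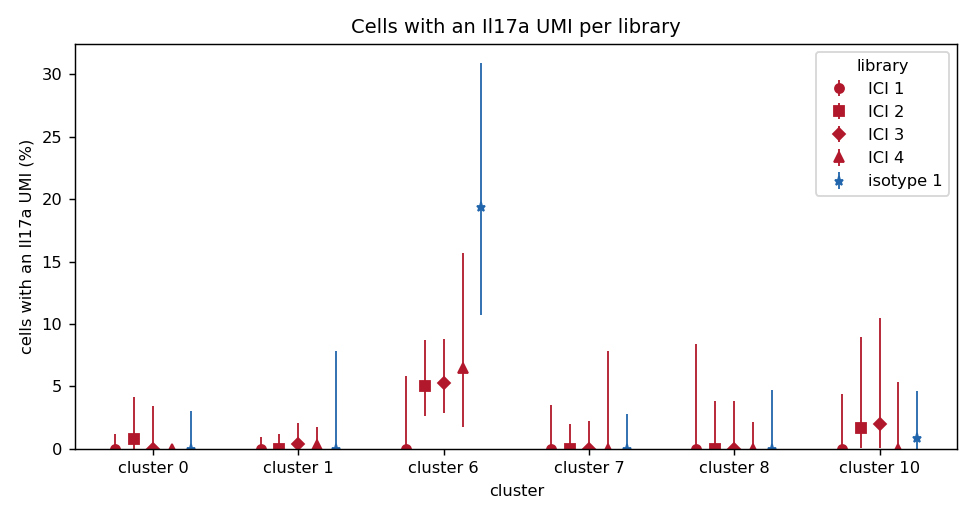
Percent of cells with an Il17a UMI (y axis) in 6 clusters (x axis), with red symbols for the 4 ICI libraries, blue for isotype and bars for exact 95% intervals. Cluster 6 stood at 4.19% on average in ICI and at 19.4% in isotype.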

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

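All tests of explanations in this part were chosen after the results were seen. Among 39 groups of 4 ICI values, 10 held a library far from the other 3, where chance gives about 5 in 100, and 3 of the 10 rest on 1 UMI each and say nothing about the library.

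ICI 4 stood apart most often. It held 32.3 M UMIs against at most 4.43 M in the other ICI libraries. Its share of T-like cluster 1 was 6.44% against at least 23.2%, that of cluster 3 was 14.6% against at most 2.92%, and that of cluster 9, led by the heat shock genes Hspa1a and Hspa1b, was 8.41% against at most 0.172%. Ctla4 over all cells was at 187 CPM in ICI 4 against at most 64.5. Il17f and Il22 were at 2.61 and 4.60 CPM in ICI 4 (80 and 141 UMIs) and at 0 in the other, less deep ICI libraries. The 3 values of 1 UMI were Krt8 in cluster 4 (0.520 CPM in ICI 4) and, in the thymocyte-like clusters, Ighg2b (4.93 CPM in ICI 1) and Tg (38.3 CPM in ICI 3).

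ICI 2 and ICI 3 shared 140 cell barcodes, a feature outside the main measurement, where other pairs of library parts shared 0 to 12. Of these barcodes, 109 were in the same cluster in both libraries. The higher of the 2 UMI totals of a shared barcode was 10.4 times the lower in the median, and where these barcodes come from was not tested. With every library part thinned to the same depth, summed profiles of ICI 2 and ICI 3 differed by a chi-square per degree of freedom of 2.93, against 2.47 between the 2 parts of ICI 4 and at least 16.3 for other pairs. Whether ICI 2 and ICI 3 come from 1 cell suspension stays open. Counted as 1 library, they leave 3 ICI libraries, a smallest exact permutation p of 0.25 and a regulatory T-like share difference of 6.51 points in place of 5.34. The SDs over 4 libraries do not allow for this.

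Class I antigen presentation genes were higher in ICI in every library over all cells and in macrophage-like cells. The test counts against different shares of the clusters as the whole cause. In 10 of 11 single clusters the list median exceeded 1 part in 4 of the all-cells median. Such a low bar leaves open that much of the all-cells difference came from cluster shares. It also says nothing about cell types mixed within a cluster. A second test counts against a few cells with very high counts: with each gene's highest cell left out the macrophage-like median was 1.26, against 1.23. Cells mixed with RNA of another lineage cannot be told apart from a change within cells, since without the cells holding T and myeloid transcripts (91 of 129 in isotype) the macrophage-like median fell to 0.60, neither near 0 nor near 1.23. A library batch or the sex of the mice, and immune checkpoint inhibition itself, cannot be told apart. ICI 4 against isotype, which were alike in Xist and red cell transcripts, gave a median of 1.33 (percentile 100 of random lists). That contrast has 1 library per group, and whether the 2 libraries share a batch is not known. The smallest exact permutation p is 0.2.

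The genes called lower outside cluster 12 include thyroid, epithelial, immunoglobulin and myeloid genes in lymphoid clusters. For the 12 results as a set, a few cells with very high counts cannot be told apart from a wider change. In the 8 that could not be tested with each highest cell left out, 97.7% to 100% of the isotype UMIs lay in 1 cell. These calls rest mainly on that cell, and leaving it out put the genes under the filter. The 4 tested had 32.2% to 72.6% in 1 cell. They kept at least 3 parts in 4 of their folds, and 1 still passed. They stayed testable because their UMIs were less concentrated, and so they say nothing about the other 8. A median of 97.9% of the isotype UMIs lay in 1 cell, against 14.4% for genes of like count. Leaving out a cell also removes a larger part of small clusters, such as the 28 isotype cells of cluster 4. No biological explanation was tested for these genes.

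The thymocyte-like share was lower in ICI. Tissue next to the thyroid carried into some libraries may contribute: the highest ICI share was 8.28 times the lowest, and Pth of the parathyroid had 5950 UMIs in isotype against at most 299 in ICI, although 93.5% of the 5950 lay in 3 cells. It cannot be told apart from immune checkpoint inhibition itself, since the smallest exact permutation p is 0.2 with 1 isotype library.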

How the results depend on the processing

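Of 177 counts of called genes under an alternative, 120 stayed within 1.5 times the main count, as did 68 of 89 counts of lists, and 147 of 173 share differences kept their direction, within 1 SD where no test was possible. A main count of 0 that stayed at 0 was counted as the same, and many of the 120 were of this kind. The 120 thus do not show that calls were stable in the sets where genes were called. Both Il17a shares stayed within 1 SD in all 6 alternatives each. Of 2220 values of named genes, 17 turned sign under a test. In ICI 4 against isotype only, a value with no test, 18 of 158 did, and 88 of 158 did so or lay more than 1 standard error from the main value. The exact permutation tests cannot pass the threshold in this design and say nothing about stability. Where a cause is not named, the cause was not tested. Cluster 12 allowed no left-out library and cycling-like cluster 5 none for ICI 2, since fewer libraries remain there. No paired analysis was possible because the labels pair no ICI library with the isotype library.

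DESeq2 called 31 genes over all cells, 52 in clusters 0, 1, 3, 4, 6 and 9 together, 5 in cluster 1, 0 in the thymocyte-like clusters, 1 in cluster 3, 8 in cluster 5, 7 in cluster 6, 15 in cluster 7 and 4 in cluster 12. Without the filter, edgeR called 5 in the joint set, 5 in cluster 1, 47 in the thymocyte-like clusters, 5 in cluster 3, 80 in cluster 4, 14 in cluster 5, 1 in cluster 6, 4 in cluster 7, 3 in cluster 8, 3 in cluster 10 and 55 in cluster 12. With ICI 1 to 3 summed it called 44 in the thymocyte-like clusters, 40 in cluster 4 and 0 in cluster 5. Thymocyte-like calls were 4 with called doublets removed and 1 with receptor, ribosomal and mitochondrial genes removed.

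With 1 ICI library left out, calls ranged from 0 to 210 over all cells, 0 to 270 in the joint set, 0 to 55 in cluster 0, 1 to 58 in cluster 1, 13 to 83 in the thymocyte-like clusters, 0 to 64 in cluster 3, 4 to 68 in cluster 4, 0 to 203 in cluster 5, 0 to 1417 in cluster 6, 0 to 647 in cluster 7, 0 to 325 in cluster 8 and 0 to 483 in cluster 10, each highest without ICI 4, where ICI 2 and 3, nearly alike, count as separate libraries. Lists called ranged from 8 to 15 over all cells, 3 to 10 in the thymocyte-like clusters, 3 to 5 in cluster 4 and 8 to 11 in cluster 6. Share differences ranged from -1.86 to 2.31 points in cluster 3, -2.32 to 2.33 in cluster 7, -0.995 to 0.780 in cluster 8, -1.77 to 0.992 in cluster 9 and -0.418 to 0.780 in cluster 14. Log2 fold changes ranged from -0.19 to 1.76 for Il17a, -0.0779 to 0.65 for Gzmb and -0.36 to 0.53 for Apoe over all cells, -0.19 to 0.25 for Themis in cluster 1 and -0.0321 to 0.37 for H2-D1 in cluster 10.

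With an estimated correlation camera called 0 lists in each of the 13 sets. A Cd3 gate turned the joint T-lineage share difference to -2.65 points. Pooling ICI cells turned that of cluster 15 to 0.108. With ICI 1 to 3 summed, Apoe over all cells was at -0.42, Themis in cluster 1 at -0.21 and Psmb8 in cluster 10 at -0.0059.

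Alternatives chosen after seeing the data follow. With ICI 2 and 3 summed, 6 genes were called in the thymocyte-like clusters and 16 in cluster 4, and Apoe was at -0.13. With the top 5% of doublet scores removed, 1 gene was called in the joint set, 4 in the thymocyte-like clusters and 0 in cluster 5, and the share differences of clusters 7 and 15 were 0.0344 and 0.127 points. With the lower copies of shared barcodes removed, 20 were called in the thymocyte-like clusters and 0 in cluster 5. With each gene's highest cell left out, calls were 1 over all cells, 0 in cluster 1, 15 in the thymocyte-like clusters, 0 in cluster 4, 0 in cluster 5 and 1 in cluster 10, lists called were 3 in cluster 1, 1 in cluster 4 and 4 in cluster 10, and Themis (-0.005), H2-Eb1 (7.09) and H2-Aa (0.21) in cluster 1 and Tubb5 (0.11) in cluster 4 turned sign. With cells holding T and myeloid transcripts removed, 8 lists were called over all cells, and Selenop over all cells (0.071) and Tubb5 in cluster 7 (0.165) turned sign. With thymocyte-like and cycling-like clusters removed, Gzmb was at -0.0494 and Apoe at -0.38 over all cells. With them out of the denominator, the share differences of clusters 3, 9 and 14 were -0.519, -0.382 and -0.194 points. With the thymocyte-like clusters added, the joint set differed by 11.9 points. In ICI 4 against isotype only, share differences were 34.3 points for the joint set, 3.11 for cluster 1, -16.2 for the thymocyte-like clusters, 10.4 for cluster 3, -0.436 for cluster 5, -3.72 for cluster 6, -8.64 for cluster 7, 6.49 for cluster 9, -7.32 for cluster 10, 1.03 for cluster 12, -0.130 for cluster 13 and 0.599 for cluster 15.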

Other observations

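The cells with an Il17a UMI in cluster 6 mostly carried gamma-delta receptor transcripts. In ICI, 24 of 29 such cells (82.8%, 95% interval 64.2 to 94.2) had a UMI of a gamma or delta constant gene and 0 of 29 had a Cd4 UMI. Other cluster 6 cells in ICI carried a gamma or delta UMI in 87.9% of cases. A Cd4 UMI was found in 63.7% of CD4 T-like cluster 0 cells in ICI, and so a cell without one can still express it. In isotype, 12 of 13 had a gamma or delta UMI and 2 of 13 had Cd4, while 53.7% of other cluster 6 cells (95% interval 39.6 to 67.4) had a gamma or delta UMI. In ICI 4 alone, 1 of 4 had a gamma or delta UMI. For background, 2.64% of macrophage-like cells in ICI had a gamma or delta UMI, at a median of 3660.5 UMIs against 3994 in the Il17a-bearing cells. In isotype, 14.7% of macrophage-like cells had one and 54.3% had a Cd4 UMI, at a median of 9932 UMIs. In ICI 4, at a median of 8726 UMIs, the shares were 6.67% and 37.8%. Depth was not equalised here.

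The authors' phase calls differed between libraries within clusters 0, 1, 3, 4, 6 and 9 together. S or G2M was called in 37.8%, 56.6%, 56.5% and 4.38% of these cells in ICI 1 to 4 and in 11.1% in isotype. Cells were not thinned for these calls and free RNA was not measured, so no cycling is read from them.

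Cells holding both T and myeloid transcripts made up 3.74%, 2.05%, 3.35% and 2.35% of ICI 1 to 4 and 11% of isotype, at unequal depth. Tg had 1736 UMIs in isotype, with 72.6% in 3 cells, and Pth had 93.5% in 3 cells. Jchain had 7427 UMIs in ICI 1, with 95.3% in 3 cells.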
